A study of Homo sapiens with 4 samples.

How the data were processed

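Total RNA of HepG2 cells was prepared with an organic reagent and a column clean-up with DNase treatment, and biotin-labelled cRNA was made for Illumina bead arrays, per the labels' protocols. There were 4 arrays, 2 of control cells and 2 of miR-24 over-expressing cells, all at 48 h. Groups were taken from the sample titles. In each group 1 title carries the word Duplicate and the other does not, and no scan date, slide or culture is given. The array without that word is called the first array here and replicate 1, and the Duplicate array replicate 2.

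The deposited scanner table holds, per the file headers, a mean bead signal and a detection p-value for each probe and array. The signals are intensity values on a linear scale, not log-transformed and not normalized between arrays as far as the values show, since the array medians differ (118 to 151 on the control arrays). Whether the authors subtracted a background is not given in the sources used here. The steps of the detection p-values are those of about 708 negative control beads per array, which were used to estimate the background. The deposited value table holds the authors' processed intensity values of 12717 targets. It is on the same linear scale with the same direction and no centring: of 11608 targets with 1 probe, 10973 equal the scanner signal within 0.1% on all 4 arrays. Its column medians were 265 and 185 for control and 244 and 173 for miR-24. It is a selection of targets whose rule is unknown, and 2015 of its rows were above background on no array.

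Signals were background-corrected with limma's neqc (normal-exponential convolution with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2). A probe was tested if its detection p was under 0.05 on both arrays of at least 1 group, which kept 10616 of 22177 probes. Gene symbols of the scanner table are old. Of the tested probes, 7913 carried a current symbol of the RefSeq table (assembly GRCh38.p14, used for names only), 47 an older symbol fixed with the gene lists and 1970 a unique synonym, and 686 kept the symbol of the file. A gene was represented by its tested probe with the highest mean signal, which mattered for 820 of 9693 genes. Among genes named from the gene lists, probes went in opposite directions for ACACA, CDKN2C and PCNA. SKP2 and TGM2, named on other grounds, had 3 tested probes each, and their probes were not compared. Adding an offset and background correction both set the scale of fold changes: without correction, fold changes of dim genes shrink.

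Groups were compared with limma (lmFit and eBayes) on the log2 values, two-sided, with Benjamini-Hochberg adjustment over all probes or genes. Gene lists, 17 in all, were fixed before the data were examined, none of them from the labels or files. Those of the genes the study followed up and of miR-24 targets named in other work came from recall of published work. All lists were tested with camera at its preset correlation of 0.01, adjusted over the 17 lists. With an estimated correlation, camera also takes its reference distribution from the residual degrees of freedom, which are few with 4 arrays. A list's median was also set against 10000 random lists of genes matched on mean signal in 20 bins. The named genes are, by a rule fixed at the same time, up to 12 of the largest changes in each direction among genes past the adjusted threshold, of which there were none, all members of the list the study followed up, and from each other list the 4 tested members with the smallest p, some of which are left out of the text. Genes named for differing in both array sets were chosen after their values were seen. For a probe below background on both arrays of a group, the fold is a bound: the other group's mean against the mean of, per array, the higher of the probe's own value and the lowest value among probes above background.

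The first arrays and the Duplicate arrays differed in brightness and in many genes. The labels do not state that the arrays of a set belong together. The values pair them: arrays of different groups differed with an SD of 0.292 and 0.312 within a set and 0.442 and 0.503 across sets. What the arrays of a set share is not given, and 2 pairs cannot tell. The sets are therefore treated as a possible technical batch that holds both groups. Values are given within each set, and with the sets as a block where that changes a call. The methods were tested on simulated data made from these arrays. With 200 of 9693 genes changed, the comparison without a block recovered 0% of genes changed 1.5-fold, 0% of those changed 2-fold and 77.8% of those changed 4-fold, and with the block 1.65%, 84.9% and 99.9%. The block fit called 6.3, 188.05 and 223.5 genes on average, of which 3.3, 169.7 and 199.8 were changed ones. A list of 45 genes shifted by 0.2 was counted as found at an unadjusted camera p under 0.05. It was found in 20 of 20 simulations with the preset correlation and in 18 with an estimated one. Simulated noise was independent between genes, whereas correlations of 0.12, 0.22 and 0.37 were estimated on the arrays for replication, repair and mitosis. The simulations therefore do not show whether calls at the preset correlation hold for co-expressed lists.

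Alternatives tried were no background correction, an offset of 50, median scaling, cyclic loess, the authors' value table, no probe filter, detection p under 0.01 on all 4 arrays, an intensity trend in eBayes, the array sets as a block, leaving out each array, a 1.5-fold minimum, the mean of a gene's probes, undetected groups raised to the lowest detected value (chosen after seeing the data), camera with an estimated correlation and fry. Tests of miR-24 seed matches in 3′ untranslated regions were planned and not run, because transcript sequences were not used here, and the files name no genome build, so no coordinates are given. The software was R 4.3.3 with limma 3.58.1.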

Results

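Messenger RNA was measured in HepG2 cells, a human liver cancer line, 48 h after transfection, in control cells and in cells that over-expressed the microRNA miR-24. MicroRNAs bind partly complementary sites in messenger RNAs, mostly in 3′ untranslated regions, and lower their stability or translation. The question was which transcripts differ in level when miR-24 is raised. Each group had 2 Illumina bead arrays, of which 1 per group is titled a duplicate. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The median raw probe signal was 151 and 118 on the control arrays and 148 and 115 on the miR-24 arrays, the second value of each being the duplicate. Of 22177 probes, 11097 and 11140 were above background on the control arrays and 10932 and 10600 on the miR-24 arrays. The probes read messenger RNA and none of them measures miR-24, so the level of miR-24 itself was not checked here.

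The arrays resembled each other by set more than by group. Over the 10616 probes tested, the first control array and the first miR-24 array differed with an SD of 0.292 on the log2 scale, and the 2 Duplicate arrays with an SD of 0.312. The 2 control arrays differed with an SD of 0.435 and the 2 miR-24 arrays with an SD of 0.460. Each set, the first arrays and the Duplicate arrays, holds 1 array of each group, so the comparison is balanced over the sets, and it is given below both pooled and within each set. Only 2 arrays per group limit the precision. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, and the tests of single genes below therefore pool the spread over genes with limma.

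No gene passed limma at an adjusted p of 0.05 among 9693 genes, nor did any of the 10616 probes. At an unadjusted p under 0.05 there were 219 genes (2.26%), 97 of them lower and 122 higher in miR-24 cells. That is a smaller share than such a threshold gives with no change, but this fit counts the difference between the array sets as spread. Its median SE was 0.224, and 0.138 with the sets as a block. With the block the count at that unadjusted p was 1254 genes (12.9%), 630 lower and 624 higher. That share is larger than the threshold gives with no change. Co-expressed genes move together, so neither share gives a number of changed genes. Again none passed after adjustment, the smallest adjusted p being 0.235. By fitted values, 97 genes were at least 1.5-fold lower and 141 at least 1.5-fold higher, of which 16 and 12 were below background in 1 group with a bound under 1.5-fold. The fitted difference reached 2-fold for 2 lower genes, MT1P3 and SLC4A10, and 4 higher ones, MYOF, S100A3, TAGLN3 and CNTFR. SLC4A10 was below background on both miR-24 arrays and CNTFR on both control arrays, so these are bounds, at least 1.56-fold lower and at least 1.52-fold higher. Median scaling in place of quantile normalization moved the median of all genes from −0.01 to −0.12 and the same counts at 1.5-fold to 202 lower and 82 higher. In simulated data of this design with 200 genes changed, the fit without a block called 77.8% of those changed 4-fold and 0% of those changed 2-fold. The fit with the block called 84.9% of those changed 2-fold and 1.65% of those changed 1.5-fold. An absence of calls therefore does not show an absence of 1.5-fold changes. These shares need not hold where fewer than 200 genes change, so they do not exclude 2-fold changes of a few genes either.

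Some genes differed by 1.5-fold or more in the same direction in both array sets, a selection made after the values were seen. They were 32 genes lower and 57 higher in miR-24 cells, while 17 were that far apart in opposite directions. Of the 32 and 57, 6 and 3 were below background on both arrays of 1 group, with a fold that is a bound under 1.5. Shuffling genes of like signal within 1 set gave a mean of 11.99 lower and 14.43 higher, and at most 27 and 30 in 10000 shuffles (permutation p = 1e-04 for both, the smallest that 10000 shuffles can give). This p treats genes as independent, and there were only 2 arrays per group. It therefore cannot exclude a swing shared by co-expressed genes. The lower genes included DNMT3B, a DNA methyltransferase, at −0.73 ± 0.27 (log2 fold change of miR-24 over control ± limma SE, 2 arrays per group, as in all values below), HMOX1, heme oxygenase 1, at −0.72 ± 0.26, SKP2, the ubiquitin ligase subunit that marks CDKN1B for degradation, at −0.65 ± 0.37, and the circadian repressor PER2 at −0.65 ± 0.23. The furthest below control was the probe for MT1P3, a metallothionein pseudogene listed as C20orf127, at −1.24 ± 0.19; it can share sequence with other metallothionein transcripts. The higher genes included the membrane repair protein MYOF at 1.12 ± 0.45, above background on 1 of 2 control arrays, the transglutaminase TGM2 at 0.95 ± 0.27, the urokinase gene PLAU at 0.84 ± 0.51 and the phosphofructokinase PFKP at 0.81 ± 0.40. None of these passed limma after adjustment over all genes (adjusted p = 1 for each). Leaving out 1 array moved 37 of the 89 by over 1.5 times, among them SKP2 (−1.03 to −0.27), PLAU (0.25 to 1.44), PFKP (0.31 to 1.31), DNMT3B (−1.01 to −0.45), HMOX1 (−0.96 to −0.47), TGM2 (0.62 to 1.27) and MYOF (0.61 to 1.63). S100A3 ranged from 0.20 to 1.89, and 3 of the 89, RGS10, HSPB8 and FHL2, crossed 0. Leaving out 1 array unbalances the sets, so these ranges take in the difference between the sets. The SEs above, from the fit without a block, take it in too. Within the sets SKP2 stood at −0.64 and −0.65 and FHL2 at 0.61 and 0.63, but all 89 were picked for a like difference in both sets. The counts depended on the processing, with 3 lower and 3 higher with no background correction and in the authors' value table, 10 and 16 with an offset of 50, 19 and 20 with a detection p under 0.01 on all 4 arrays, and 73 and 23 with median scaling.

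**Figure D1:**
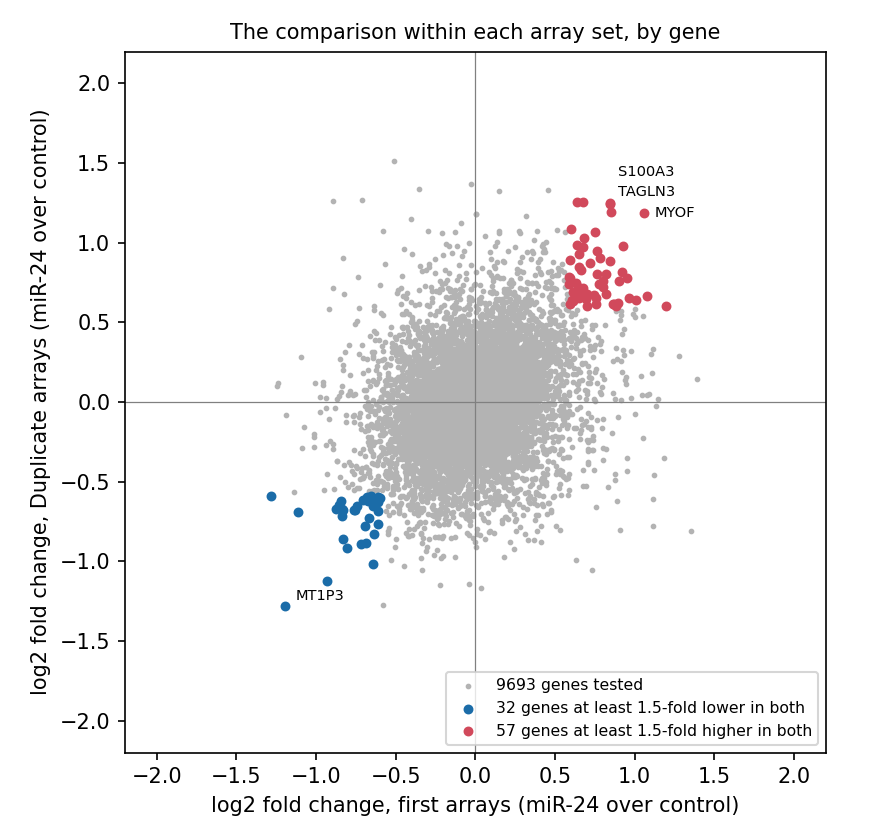
Log2 fold change of miR-24 over control for each of 9693 genes on the first arrays (x axis) and on the Duplicate arrays (y axis), 1 array of each group per axis. Blue points are, by fitted values, the 32 genes at least 1.5-fold lower and red points the 57 genes at least 1.5-fold higher on both axes; MT1P3 lies furthest below 0 by the mean of both, at −1.20 and −1.28.

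A list of cell cycle genes, called here the genes the study followed up, was lower in miR-24 cells. The list was fixed before the data were examined from recall of published work on miR-24, and neither the labels nor the files name its genes. The mean of all 18 measured members lay below control, and 16 were lower in both array sets. The median was −0.32 (1.25-fold lower), with −0.21 on the first arrays and −0.40 on the Duplicate arrays. CDK1, the mitotic kinase, listed under its older name CDC2, stood at −0.43 ± 0.19, with mean log2 signals of 10.07 ± 0.11 in control and 9.64 ± 0.09 in miR-24 cells (SD, n = 2). CCNB1, the cyclin B1 that activates it, stood at −0.38 ± 0.21, MCM10, a replication initiation factor, at −0.47 ± 0.22, and MCM4, part of the replicative helicase, at −0.44 ± 0.24. E2F2, a transcription factor of the G1/S transition, was at −0.30 ± 0.18. MYC was at −0.63 ± 0.35, and the sets differed, with −1.19 on the first arrays and −0.08 on the Duplicate arrays. CDKN1B, the cyclin-dependent kinase inhibitor p27, stood at −0.44 ± 0.18, and VHL, the ubiquitin ligase subunit that marks HIF for degradation, at −0.38 ± 0.21. AURKB was at −0.33 ± 0.28, BRCA1 at −0.25 ± 0.30, RRM2 at −0.29 ± 0.24, CDCA7 at −0.38 ± 0.24 and H2AX, listed as H2AFX, at −0.31 ± 0.24. The smallest differences were those of CCNA2 at −0.17 ± 0.22, FEN1 at −0.23 ± 0.25, CDK4 at −0.12 ± 0.27, PCNA at −0.09 ± 0.20 and CHEK1 at −0.09 ± 0.23. Besides MYC, the sets differed for, among others, MCM4 (−0.12 on the first and −0.76 on the Duplicate arrays) and AURKB (−0.03 and −0.63). They also did for FEN1 (−0.03 and −0.42) and RRM2 (−0.09 and −0.48).

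None of the 18 passed limma singly, over all genes or adjusted over the list alone (smallest adjusted p = 0.322). As a group they fell, by camera with its preset correlation (adjusted p = 8.6e-07 over 17 lists), a call that ended with an estimated correlation (adjusted p = 0.433). The published work recalled is taken to have picked these genes in part on these same arrays. Neither the direction of the members nor the camera p of this list is therefore independent evidence. The median was −0.52 without the first control array and −0.20 without the Duplicate control array. Leaving out 1 array, which unbalances the sets, moved the value of 56 of the 74 genes named from all lists by over 1.5 times.

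**Figure D2:**
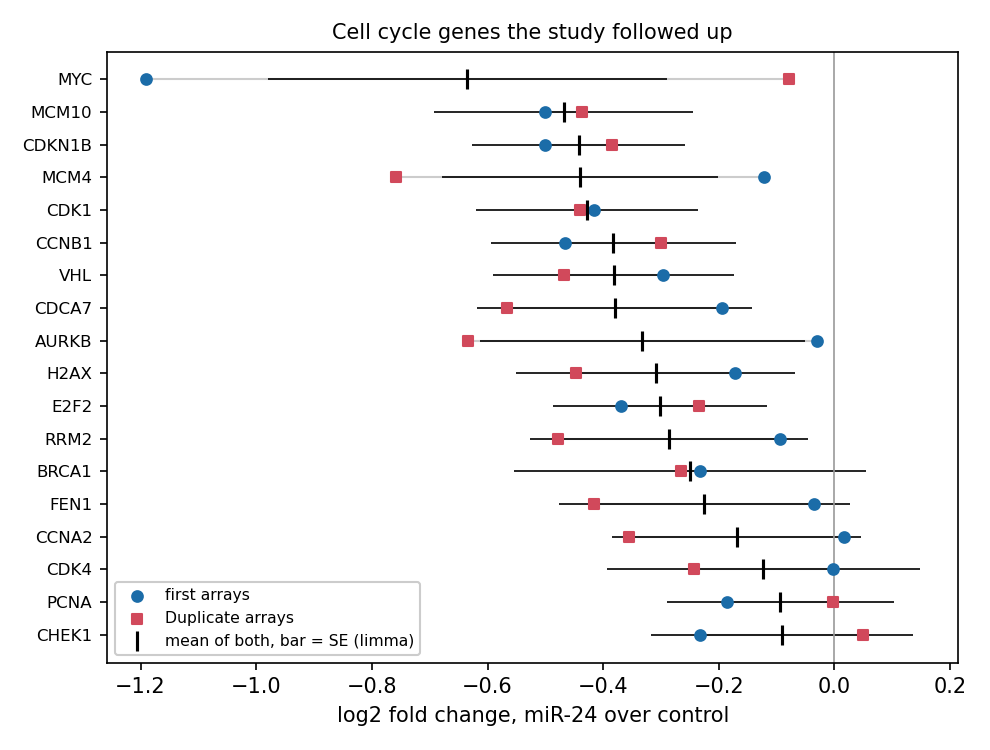
Log2 fold change of miR-24 over control (x axis) for the 18 cell cycle genes the study followed up; blue circles are the first arrays, red squares the Duplicate arrays, black ticks the mean of both with the limma SE as a bar. The ticks of all 18 genes lie below 0, from −0.63 for MYC to −0.09 for CHEK1.

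Genes of DNA replication, mitosis and DNA repair were also lower on average, by less than the genes above. Of 44 replication genes, 36 had a mean below control, and the median was −0.21 (−0.13 on the first arrays, −0.24 on the Duplicate arrays). PRIM1, the catalytic subunit of DNA primase, was at −0.43 ± 0.22, whereas PRIM2, the other primase subunit, was at 0.51 ± 0.22. CDC6, which loads the helicase, was at −0.42 ± 0.23 and above background on 1 of 2 miR-24 arrays. Of 49 mitosis genes, 42 had a mean below control, with a median of −0.17 (−0.18 and −0.22 within the sets). The kinase NEK2 was at −0.60 ± 0.23, BIRC5, which encodes survivin, at −0.46 ± 0.24 and the ubiquitin-conjugating enzyme UBE2C at −0.42 ± 0.22. Of 50 repair genes, 36 had a mean below control, with a median of −0.14 (−0.13 and −0.17 within the sets). The damage-response adaptor MDC1 was at −0.46 ± 0.19, the kinase ATM at −0.48 ± 0.26 and FANCG of the Fanconi pathway at −0.45 ± 0.23.

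All 3 lists fell by camera, with adjusted p = 1.8e-04 for replication, 5.0e-04 for mitosis and 0.0023 for repair. With an estimated correlation the adjusted p was 0.433 for replication and 0.559 for mitosis and for repair. No member passed limma over all genes or adjusted over its list alone. Of their members, 5 replication, 4 mitosis and 3 repair genes are also on the list the study followed up. Between the sets, the medians on the Duplicate arrays were 0.14, 0.34 and 0.21 above the first arrays for replication, mitosis and repair (camera adjusted p = 0.063, 6.1e-07 and 4.4e-04, and adjusted p = 0.859, 0.563 and 0.563 with an estimated correlation), and leaving out 1 array unbalances the sets. Without the Duplicate control array the medians were −0.09, 0.02 and −0.02 for replication, mitosis and repair and none was called, and without the first miR-24 array they were −0.13, 0.03 and −0.04, of which replication kept its call. Without the first control array the mitosis and repair medians were −0.34 and −0.29, and without the Duplicate miR-24 array −0.35 and −0.28.

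Regulators of G1, the phase before DNA synthesis, went both ways. Of 32 tested cyclins, CDKs, inhibitors and E2F and RB family members, 19 lay below control and 13 above, with a median of −0.04 (0.00 and −0.12 within the sets, camera adjusted p = 0.516). CCND3, cyclin D3, was at 0.68 ± 0.31, and CDKN2C, the CDK4 and CDK6 inhibitor p18, at 0.68 ± 0.23 by its brightest probe and at −0.32 by a second, dimmer one. None passed limma over all genes or adjusted over the list alone, and with the array sets as a block 3 passed over the list alone, CCND3 and CDKN2C, which were higher, and SKP2, which was lower. Targets of p53 did not shift as a list either, with 12 of 22 below control, a median of −0.03 (−0.04 and −0.06 within the sets) and a camera adjusted p of 0.516. SESN1 was at −0.55 ± 0.19, MDM2, the ubiquitin ligase of p53, at −0.45 ± 0.21, PHLDA3 at −0.28 ± 0.22 and CDKN1A, the inhibitor p21, at 0.22 ± 0.19. Of 29 MYC targets in ribosome biogenesis, 20 lay below control, with a median of −0.11 (−0.09 and −0.12 within the sets), which did not pass (camera adjusted p = 0.057). The nucleolar proteins NOP56, listed as NOL5A, and NOP58 were at −0.56 ± 0.19 and −0.39 ± 0.26, NOC4L was at −0.33 ± 0.20 and the chaperonin HSPD1 at −0.29 ± 0.23. That list passed in 9 of the alternative settings with all 4 arrays, among them no background correction (adjusted p = 0.015) and median scaling (0.020), and 4 of the 9 were chosen after seeing the data. It did not pass with an estimated correlation (adjusted p = 0.433, and 0.509 with the block too) or by fry (0.491).

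Transcripts listed, from recall, as miR-24 targets named in other work were lower. Of 19 tested, 15 had a mean below control, with a median of −0.23 (−0.12 and −0.26 within the sets). TOP1, DNA topoisomerase I, was at −0.70 ± 0.30 (−0.34 and −1.05 within the sets), the activin receptor ACVR1B at −0.50 ± 0.20 and the kinase PAK4 at −0.30 ± 0.20. CDKN1B and H2AX, above, are on this list too. The list fell by camera (adjusted p = 0.0023), with an adjusted p of 0.433 with an estimated correlation. The estimate was −0.017, below the preset 0.01, so that loss comes from the few residual degrees of freedom. No member passed limma over all genes or adjusted over the list alone. The call ended without the Duplicate control array (median −0.15, adjusted p = 0.098) and without the Duplicate miR-24 array (median −0.26, adjusted p = 0.059). The 17 genes of microRNA processing and silencing did not shift together, with 7 below and 10 above control and a camera adjusted p of 0.658. Their median was 0.02 and their mean −0.06, the camera test pointing the way of the mean, and the within-set medians were 0.00 and −0.07. The members with the smallest p were all lower in miR-24 cells. They were the decapping enzyme DCP2 at −0.79 ± 0.41, the decapping cofactor DCP1A at −0.47 ± 0.19, LSM14A at −0.49 ± 0.22 and AGO1, an Argonaute protein listed as EIF2C1, at −0.57 ± 0.32. With 1 array left out, which unbalances the sets, DCP2 ranged from −1.26 to −0.31 and AGO1 from −0.99 to −0.15. None passed limma over all genes or adjusted over the list alone, and with the array sets as a block DCP2 passed over the list alone.

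Genes of the unfolded protein and integrated stress responses were higher in miR-24 cells. Of 28 tested, 22 had a mean above control and 19 were higher in both array sets, with a median of 0.18 (1.13-fold; 0.12 and 0.15 within the sets). SLC7A11, the cystine transporter, was at 0.61 ± 0.32 and above background on 1 of 2 control arrays, HERPUD1, of endoplasmic reticulum degradation, was at 0.44 ± 0.24, the transcription factor CEBPB at 0.35 ± 0.19 and HSPA5, the chaperone BiP, at 0.26 ± 0.19. The list rose by camera (adjusted p = 0.0086), with an adjusted p of 0.433 with an estimated correlation. The estimate was −0.030, below the preset 0.01, so that loss comes from the few residual degrees of freedom. No member passed limma over all genes or adjusted over the list alone. The call ended without either control array (medians 0.11 and 0.19) and without the Duplicate miR-24 array (0.06), and median scaling lowered the median to 0.04 while all genes moved to −0.12.

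Hypoxia and interferon lists leaned the same way without passing. Of 27 hypoxia and HIF targets, 18 lay above control, with a median of 0.14 (0.09 and 0.13 within the sets, camera adjusted p = 0.107). The carbonic anhydrase CA12 was at 0.45 ± 0.24, above background on 1 of 2 control arrays, while the glucose transporter SLC2A3 was at −0.53 ± 0.20. Of 21 interferon response genes, 16 lay above control, with a median of 0.07 (0.06 and 0.16 within the sets, camera adjusted p = 0.065), and the list passed in 4 alternative settings with all 4 arrays, among them the array sets as a block (adjusted p = 0.032), and did not pass with an estimated correlation (adjusted p = 0.559, and 0.509 with the block too). The exonuclease ISG20 was at 0.55 ± 0.30, IFITM3 at 0.26 ± 0.20 and IFITM2 at 0.36 ± 0.29. OAS2 was below background on both control arrays and above it on both miR-24 arrays, at least 1.29-fold higher, the control being set at the lowest signal above background where its own was lower. No member of either list passed limma over all genes or adjusted over the list alone. Median scaling turned the interferon median to −0.06, with all genes at −0.12.

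Liver functions did not shift as lists. Of 34 hepatocyte secreted proteins and transcription factors, 19 lay below control and 15 above, with a median of −0.02 (−0.02 and −0.08 within the sets, camera adjusted p = 0.558). The bile acid receptor NR1H4 was at −0.61 ± 0.25, the pioneer factor FOXA1 at −0.27 ± 0.21 and haptoglobin, HP, at 0.46 ± 0.34. With 1 array left out, which unbalances the sets, FOXA1 ranged from −0.44 to −0.10 and HP from 0.03 to 0.88. Of 28 genes of cholesterol and fatty acid synthesis, 16 lay below control and 12 above, with a median of −0.04 (−0.13 and −0.08 within the sets, camera adjusted p = 0.516). ACACA, acetyl-CoA carboxylase 1, was at −0.35 ± 0.25, the cholesterol synthesis enzyme EBP was at −0.22 ± 0.19, and the desaturase FADS2, above background on 1 of 2 control arrays, was at 0.50 ± 0.40. None passed limma over all genes or adjusted over its list alone. The lipid list was called lower without the first control array (median −0.40) or the Duplicate miR-24 array (−0.36) and higher without the Duplicate control array (0.23) or the first miR-24 array (0.20). The hepatocyte list was called lower without the first control array (−0.12) or the Duplicate miR-24 array (−0.19).

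Histone genes were higher in miR-24 cells, with 10 of 11 means above control and a median of 0.22 (0.17 and 0.16 within the sets). H1-2, listed as HIST1H1C, was at 0.55 ± 0.42 and H2AC6, listed as HIST1H2AC, at 0.25 ± 0.28. H2AZ1, at −0.25 ± 0.18, encodes a variant made outside S phase too. The list rose by camera (adjusted p = 0.049), with an adjusted p of 0.559 with an estimated correlation. The call ended with no background correction (median 0.11), in the authors' value table (0.10) and with either other probe filter (0.14 for both), and the median was −0.03 without the Duplicate control array, 0.04 without the first miR-24 array, 0.46 without the first control array and 0.38 without the Duplicate miR-24 array.

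Markers of other cell types were mostly below background. Of 19 fibroblast markers, 3 were tested and all 3 means lay above control in miR-24 cells, with a median of 0.57, or 0.27 with FBN1 at its bound (within-set medians 0.12 and 0.58 with FBN1 at its bound). TAGLN, transgelin, was at 0.57 ± 0.18 and was expressed in control cells too, at a log2 signal of 10.17 ± 0.01 (SD, n = 2). FBN1, fibrillin 1, was below background on both control arrays and at least 1.16-fold higher in miR-24 cells. DCN, decorin, was at 0.27 ± 0.34 and above background on 1 control array. None passed limma over all genes, and over the list alone FBN1 and TAGLN passed by fitted values (smallest adjusted p = 0.033), none with FBN1 at its bound (0.064), and TAGLN with FBN1 at its bound and the array sets as a block (0.013). The list, of which FBN1 and DCN entered only through the miR-24 arrays, rose by camera (adjusted p = 8.9e-04, and 0.013 with FBN1 at its bound), with an adjusted p of 0.433 with an estimated correlation. The call ended without a probe filter (median 0.04) and without the Duplicate array of control (0.58, adjusted p = 0.098) or of miR-24 (0.56, adjusted p = 0.054). Of 20 erythroid and blood cell markers, 4 were tested, with a median of −0.21, or −0.16 with HBA1 at its bound (within-set medians −0.08 and 0.01 with HBA1 at its bound, camera adjusted p = 0.142 by fitted values and 0.365 with HBA1 at its bound). HBA1 was below background on both miR-24 arrays, and control was at least 1.09-fold higher. SPI1 was at −0.23 ± 0.27, KLF1 at −0.19 ± 0.24 and LYZ at 0.05 ± 0.20, the last of which was at −0.05 with median scaling, which put all genes at −0.12, and none passed limma over all genes or adjusted over the list alone.

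**Figure D3:**
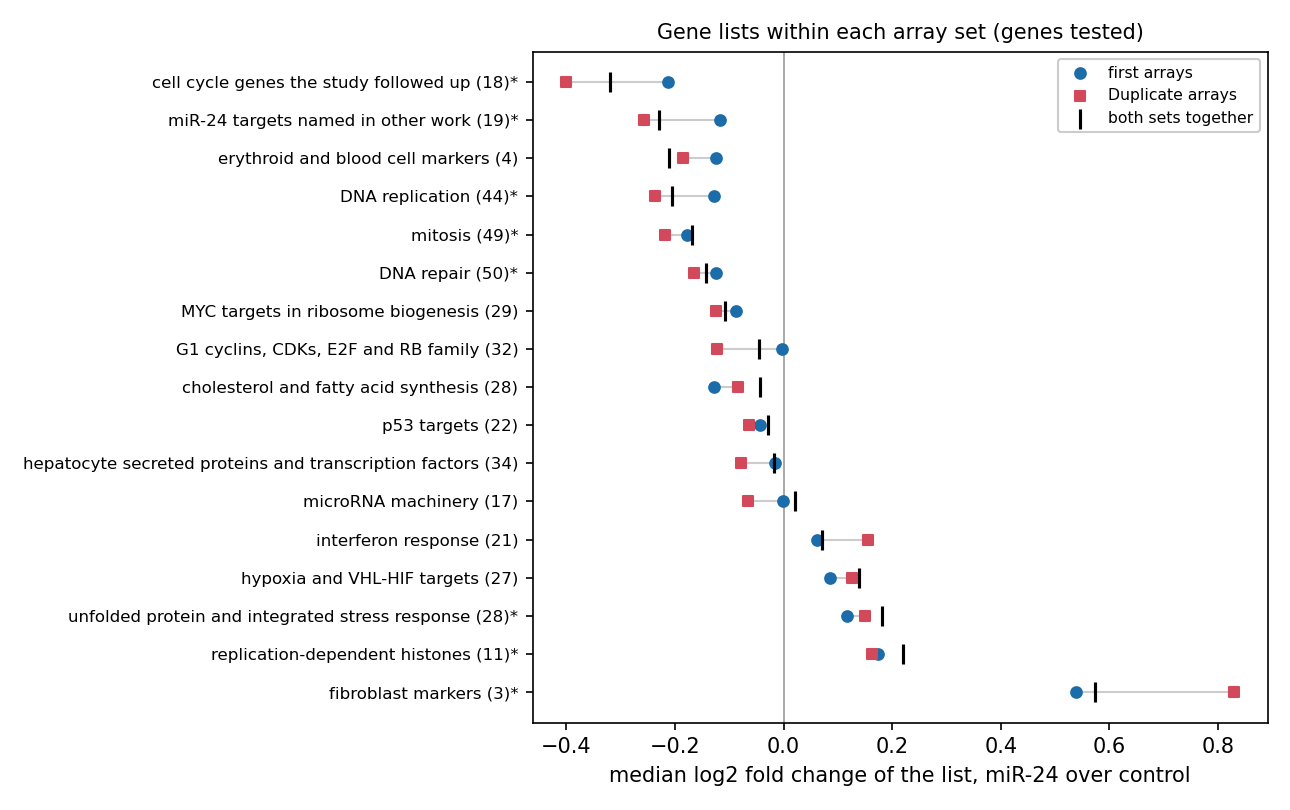
Median log2 fold change of miR-24 over control (x axis) for the 17 gene lists, with the number of genes tested in parentheses; blue circles are the first arrays, red squares the Duplicate arrays and black ticks both together, and an asterisk marks the 8 lists past an adjusted p of 0.05 by camera with its preset correlation. The list the study followed up lies furthest below 0 at −0.32 and the fibroblast markers furthest above at 0.57, or 0.27 with FBN1 at its bound.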

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

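The combined tests with the block and an estimated correlation, the estimated correlation entered as a fixed value, the lists without the study's genes, cyclic loess for lists, undetected groups at the lowest detected value with and without the block, and all settings for array agreement and for genes in both sets were chosen after seeing the data. The count of genes passing limma stayed at 0 in every setting tried. The genes at an unadjusted p under 0.05 numbered 219, and 1254 with the replicate block, 525 with no probe filter, which tests 18128 genes, and 108 without the Duplicate control array. Arrays of the same set deviated from their group means together (r = 0.665 across probes, which are not independent), and the labels do not say what they share. The block ended no list call and added 1, the interferon list (median 0.07). Of 17 lists, 8 passed in the main setting and 7 to 9 under the other normalizations, tables, filters and the block. The count was 0 with an estimated correlation, with fry and with the block and an estimated correlation, 5 with the estimated correlation as a fixed value, and 2 to 10 when 1 array was left out, the 2 being without the Duplicate control array. Estimated correlation, fry, and the block with an estimated correlation leave the medians as they were, and all 8 lost their calls at −0.32 for the genes the study followed up, −0.21 for replication, −0.17 for mitosis, −0.14 for repair, 0.18 for the stress responses, −0.23 for miR-24 targets of other work, 0.22 for histones and 0.57 for fibroblast markers. Entered as a fixed value, negative estimates being set to 0, the estimated correlation ended the calls of replication, mitosis, repair and histones. The genes the study followed up kept theirs at 0.18, so part of their loss above comes from the few residual degrees of freedom. The stress responses and miR-24 targets kept theirs at 0, their estimates being −0.030 and −0.017. Those lie below the preset 0.01, so the loss of these 2 lists with the estimated correlation comes from the residual degrees of freedom. With the block the fixed value ended, among the 8 main calls, that of the fibroblast markers alone. It also ended the interferon call that the block had added, at a value of 0.14, and calls of lower lists went from 5 to 6. With the block the fixed value was 0 for mitosis, repair, histones, the stress responses, miR-24 targets and the study's genes. A value of 0 is more lenient than the preset 0.01, so that those calls stayed shows nothing about correlation. Replication kept its call at 0.098. Histones also lost their call with no background correction (0.11), in the authors' value table (0.10) and with no filter or the stricter one (0.14), and fibroblast markers with no filter (0.037). The MYC list gained a call in 9 settings. With undetected groups at the lowest detected value no list lost its call, and the fibroblast median was 0.27. Without 1 array, medians ranged from −0.29 to −0.090 for replication, −0.35 to 0.027 for mitosis, −0.29 to −0.019 for repair, 0.065 to 0.19 for the stress responses, −0.28 to −0.15 for miR-24 targets, −0.034 to 0.46 for histones and 0.56 to 0.66 for fibroblast markers. Among lists with no call the ranges that crossed 0 were −0.19 to 0.046 for G1, −0.19 to 0.12 for hepatocyte genes, −0.40 to 0.23 for lipid synthesis and −0.17 to 0.18 for microRNA machinery. Such a fit is no longer balanced over the array sets, and the lone array of a group is assumed to vary like the others. Medians of uncalled lists also changed sign for p53 targets with the stricter filter (0.012), interferon genes with median scaling (−0.057), microRNA machinery with median scaling (−0.095) and in the authors' table (−0.0073), and blood markers with no filter (0.00088). Median scaling moved all genes, to a median of −0.12, and the cause of the other changes was not tested.

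Named genes kept their sign in 722 of 723 values under settings with all 4 arrays, LYZ with median scaling (−0.045), which moved all genes, being the exception, and in 279 of 296 values with 1 array left out. The ranges that crossed 0 were −0.68 to 0.019 for AURKB, −0.54 to 0.045 for BRCA1, −0.36 to 0.021 for CCNA2, −0.41 to 0.16 for CDK4, −0.30 to 0.12 for CHEK1, −0.13 to 0.66 for DCN, −0.015 to 1.01 for FADS2, −0.50 to 0.050 for FEN1, −0.018 to 1.11 for H1-2, −0.072 to 0.58 for H2AC6, −0.40 to 0.010 for KLF1, −0.053 to 0.16 for LYZ, −0.21 to 0.023 for PCNA and −0.53 to 0.070 for SPI1. In all, 56 of 74 named genes moved by over 1.5 times with 1 array left out, a fit that is unbalanced over the sets. Among those that kept their sign the moves were large for, among others, TOP1 (−1.09 to −0.30), AGO1 (−0.99 to −0.15), DCP2 (−1.26 to −0.31), MYC (−1.12 to −0.15), HP (0.030 to 0.88), FOXA1 (−0.44 to −0.097), RRM2 (−0.54 to −0.033), H2AX (−0.55 to −0.069), HSPD1 (−0.50 to −0.085) and IFITM2 (0.090 to 0.64). They were also large for ACACA (−0.58 to −0.13), CDCA7 (−0.63 to −0.13), NOP58 (−0.65 to −0.13) and ATM (−0.77 to −0.19). The SD between arrays of a group, 0.447 on average, was 0.291 with no background correction, 0.368 with an offset of 50, 0.288 in the authors' table, 0.362 with no filter and 0.421 with the stricter filter. Genes at least 1.5-fold lower and higher in both sets, 32 and 57, numbered 3 and 3 with no background correction and in the authors' table, 10 and 16 with an offset of 50, 73 and 23 with median scaling and 19 and 20 with the stricter filter. More genes than in shuffles of genes of like signal were found in each of these settings (permutation p at most 2.0e-04). The shuffles treat genes as independent, so a swing shared by co-expressed genes is not excluded. Signals near background limit dim genes most. The seed-match tests were not run, since they need transcript sequences not used here.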

Other observations

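All tests of an explanation in this part were chosen after the results were seen. The 2 arrays of a group differed in many genes as well as in brightness. Of 9693 genes, 1545 differed between the Duplicate and the first arrays at an adjusted p under 0.05 (limma with group and array set as terms), 790 higher and 755 lower on the Duplicate arrays. Genes of cholesterol and fatty acid synthesis were higher there, with 21 of 28 higher in both groups and a median difference of 0.70 in control and 0.62 in miR-24 cells (camera adjusted p = 6.7e-08, and 0.563 with an estimated correlation). HMGCS1 was 1.13 higher and the sterol-responsive factor SREBF2 0.97, while CYP51A1 differed by −0.56 (log2, mean of both groups). The metallothionein MT1G was 2.25 higher on the Duplicate array in control and 2.35 in miR-24 cells, with MT1F at 1.40 and 1.29 and MT2A at −0.52 and −0.27.

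Mitosis genes were 0.34 higher on the Duplicate arrays by their median (camera adjusted p = 6.1e-07), hepatocyte genes 0.26 higher (1.7e-04), DNA repair genes 0.21 higher (4.4e-04), and histone genes differed by −0.30 (0.038). With an estimated correlation none of these lists passed (adjusted p = 0.563 for the first 3 and 0.778 for histones). Among single genes, the centromere protein CENPF was 1.49 and the kinesin KIF15 1.57 higher on the Duplicate arrays, and the fatty acid binding protein FABP1 1.31. The proteoglycan VCAN differed by −2.08, SPINK1 by −2.04 and S100A11 by −1.98.

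The shift of lipid synthesis genes between array sets was tested against 2 technical explanations. The Duplicate arrays were dimmer, but 0 of 10000 random lists matched on signal reached the observed median, the highest being 0.286, which argues against a signal-level effect. A single array that stands apart is argued against by the smaller of the 2 groups' medians, 0.623, where the 97.5th percentile of matched lists was 0.149. The sets may come from cultures that differed in growth or medium, or from separate preparations. The labels name neither, so no biological explanation was tested.

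The lower level of replication, mitosis and repair genes in miR-24 cells was weighed as 143 pooled genes, with a median of −0.16 over all 4 arrays, −0.13 on the first arrays and −0.22 on the Duplicate arrays. A bias with signal level is argued against, since 0 of 10000 matched lists had so low a median, the lowest being −0.08. A swing of co-expressed growth genes between cultures, unrelated to miR-24, stays open: the same genes were 0.23 higher on the Duplicate arrays, and a random swing shifts both sets the same way with a probability of 0.5. With the sets as a block, camera gave p = 1.6e-08 at its preset correlation and p = 0.109 with an estimated correlation of 0.0092, a loss that comes from a reference distribution with 1 residual degree of freedom, and without a block p was 1.8e-07 and 0.297. The effect of miR-24 and such a swing cannot be told apart with 2 arrays per group, and that miR-24 lowers these transcripts remains a hypothesis.

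FBN1 and TAGLN were higher on both miR-24 arrays, and fibroblasts mixed into the miR-24 samples could bring such transcripts. Of 6 transcripts abundant in fibroblasts, COL1A1, COL1A2, COL3A1, LUM, SPARC and VIM, 0 were above background on both miR-24 arrays. COL1A1 was above it on the Duplicate miR-24 array alone, at a detection p of 0.027. This argues against fibroblasts as the source. TAGLN is expressed by control HepG2 cells as well, and a change within the HepG2 cells stays open and was not tested further.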
